A study of Mus musculus with 11 samples.

How the data were processed

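RNA from punches of cerebral cortex of 11 mice was sequenced as one library per animal, with 4 controls, 4 Prkci cKO and 3 Prkcz cKO; the series design describes the replicates of each genotype as biological. One table of 16228 genes by 11 libraries was used. Per the submitters' processing notes, reads were handled with FastQC, Trim Galore, STAR, RSEM and edgeR on GRCm38; versions and the gene annotation are not given in the sources used here. The authors deposited a normalised expression signal per gene and library, scaled by library size, with columns that sum to between 1021767 and 1082562. The values carry 2 decimals, and how each library was scaled is not given in the sources used here.

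Between 86.6% and 89.4% of values under 0.5 lay within 0.005 of a whole multiple of one step per library, so the step gave an estimate of relative depth, but whole reads were not recovered for nearly all genes and no count test was run. The effective depth was between 14810000 and 28170000 reads. The share of the column sum taken by Rn45s, a ribosomal RNA precursor, was 1.12% to 4.75%. Replicates of one group correlated at r = 0.992 to 0.996 on the log scale, and at most 0.33% of values were identical in any pair, so no library was taken for a repeat of another.

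Genes with a value of at least 1 in at least 3 libraries were kept, which left 14330 of 16228. Values were taken as log2(value + 0.5), a scale that understates the change of low genes. All 11 libraries entered one fit with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, 8 residual degrees of freedom) with a term per genotype and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method over genes, with 0.05 as the threshold. Values in the text are means ± SD over libraries, and changes are limma coefficients with their standard errors. The controls were also coded by genotype label in a fit of 4 groups. Cre and genotype line coincide with the groups, so the comparisons with controls cannot separate them. The comparison between the knockouts cannot separate the kinase from the line.

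Before the data were examined, 35 lists of cell type, pathway, tissue quality and contamination genes were fixed, of which 34 had members to test. Lists were tested with camera at a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry, whose test asks whether a list's genes move one way on balance. Calls in the text are camera calls with the preset correlation. With an estimated correlation, 1 of 16 calls held in Prkci cKO, 2 of 16 in Prkcz cKO and 0 of 11 between the knockouts; fry called 8, 10 and 3 lists. Named genes were fixed by rule: Prkci and Prkcz, the 10 largest changes in each direction among genes past the threshold with a mean log2 value of at least 2 and no overlap between the groups, the smallest p-values up to 5 where fewer passed, and up to 4 members of each list with the smallest p. Unnamed gene models were counted and not described. Some genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen.

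Symbols are those of the deposited table. Of 16228, 15569 matched GENCODE M21 or RefSeq synonyms on GRCm38, the build of the submitters' notes, and 659 did not; 23 names were date-like. Positions come from that annotation. Whether reads were counted by strand is not given in the sources used here, so genes that overlap another are uncertain.

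Chance similarity of the comparisons was obtained from 100 permutations of the residuals of the libraries among the groups; an earlier version drew libraries with replacement, which placed copies of one library in several groups, and was dropped after its results were seen. Alternatives covered the pseudocount, the filter, scaling, the variance model, the samples fitted, the controls by genotype, a replicate block and leaving out each library. On simulated data with 14330 genes, log2 changes of 0.5 were recovered for 80.0% of genes in Prkci cKO against controls, 79.0% in Prkcz cKO against controls and 73.0% between the knockouts, and changes of 1 for 97.0%, 94.0% and 95.0%. In these simulations 8, 7 and 13 unchanged genes were called. The simulated noise was independent between genes, without variation shared within a library, so recovery in the real data may be lower. Figures were drawn with matplotlib.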

Results

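Gene expression was measured by bulk RNA sequencing of total RNA from punches of mouse cerebral cortex taken at postnatal day 30. The series asked how the atypical protein kinase C paralogs PRKCI and PRKCZ, enzymes of cell polarity, act in the oligodendrocyte lineage, the cells that make myelin in the brain. The genotypes compared were 4 controls without Cre, 4 animals with Ng2-Cre and floxed Prkci (Prkci cKO), and 3 animals with Ng2-Cre and floxed Prkcz (Prkcz cKO). Ng2-Cre is a recombinase driven by regulatory sequence of Cspg4, which encodes the NG2 proteoglycan of oligodendrocyte precursors. In which cells it acted, within or outside the oligodendrocyte lineage, was not examined here. Among the controls, replicates 1 and 2 were labelled Pkcz f/+ and replicates 3 and 4 Pkcz f/f. No control of the Prkci line and no control with Cre was among these samples. The effective depth read from the steps of low values was about 14810000 reads in Prkcz cKO replicate 3 and between 20620000 and 28170000 in the other libraries. All 11 libraries had high Ddx3y (50.5 to 64.8) and Xist of at most 0.11, the pattern of males.

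The targeted genes were examined first, to check the labels. Prkci (chromosome 3, 30995747 to 31052959, GRCm38) was 67.0 ± 1.47 (SD, n = 4) in Prkci cKO against 87.8 ± 2.52 (SD, n = 4) in controls. It fell by 0.39 on the log2 scale (SE 0.045, limma adjusted p = 9.84e-04), a change of -23.5%, and was lower in 4 of 4 libraries than in any control. In Prkcz cKO, Prkci was 86.1 ± 4.79 (SD, n = 3), with a log2 change of -0.03 (SE 0.048, adjusted p = 0.808). Prkcz (chromosome 4, 155260129 to 155361361) was 278 ± 15.1 (SD, n = 3) in Prkcz cKO against 323 ± 20.2 (SD, n = 4) in controls. Its log2 change of -0.22 (SE 0.055) did not pass the threshold (adjusted p = 0.0966), although all 3 libraries lay below every control. Prkcz in Prkci cKO had a log2 change of -0.04 (SE 0.051, adjusted p = 0.842). The values are sums over a whole gene in whole tissue, and the floxed exons were not examined separately here.

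**Figure D1:**
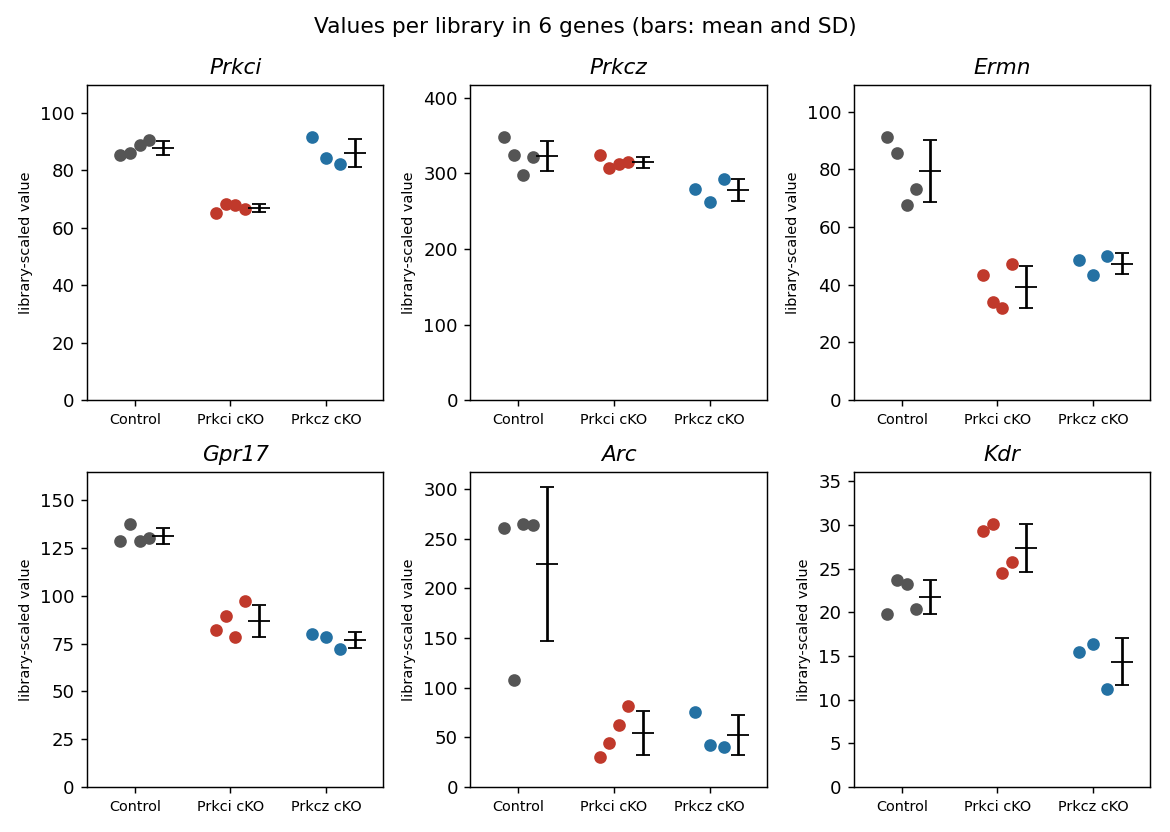
Library-scaled expression values as deposited (vertical axes, from 0) of 6 genes in each library of the 3 genotypes, with the mean and SD beside the points. Prkci lies between 65.0 and 68.3 in the 4 Prkci cKO libraries and at 82.4 or above in all others, and every knockout library lies below every control library for Ermn, Gpr17 and Arc.

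The first comparison asked what changed in cortex when Prkci was floxed in NG2 lineage cells. Myelin genes were lower in Prkci cKO than in controls. Ermn, a cytoskeletal protein of myelinating cells, fell by 1.02 (log2, SE 0.120), Adamts4 by 0.99 (SE 0.117) and Cldn11, the tight junction protein of myelin, by 0.98 (SE 0.115), each with a limma adjusted p of 9.84e-04 (n = 4 against 4). Aspa, which cleaves N-acetylaspartate in oligodendrocytes, fell by 0.91 (SE 0.102). Mbp, chosen after its values were seen, had a log2 change of -0.81 (SE 0.207) that did not pass (adjusted p = 0.0750).

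Of 40 measured genes of the mature oligodendrocyte and myelin list, 26 fell and none rose over all genes tested, and 35 fell when adjusted over the list alone. The list mean was -0.65 (camera adjusted p = 1.55e-48; adjusted p = 0.0966 with an estimated correlation). Of 24 newly formed oligodendrocyte genes, 14 fell (19 adjusted over the list alone), with a mean of -0.47, and this list alone kept its call with an estimated correlation (adjusted p = 0.00658). Its members included Gpr17, a receptor of differentiating oligodendrocytes, at 87.0 ± 8.29 against 131 ± 4.19 (SD, n = 4 each; log2 change -0.60, adjusted p = 8.08e-04), Cnksr3 (-0.61), Sirt2 (-0.52) and Plxnb3 (-0.84). Of 20 myelin regulatory transcription factors 9 fell, with a mean of -0.27 (adjusted p = 0.0966 with an estimated correlation): Sox10 (-0.69), Olig1 (-0.54), Nkx6-2 (-1.01) and Zfp488 (-0.83) were among them. In the sphingolipid and fatty acid synthesis list, 6 of 25 genes fell and the mean was -0.22 (adjusted p = 0.125 with an estimated correlation). Ugt8a and Fa2h, enzymes of galactolipid synthesis, fell by 0.86 and 0.87, and the fatty acid elongase Elovl7 by 0.64. Of 24 oligodendrocyte precursor genes 3 fell (6 lower and 1 higher adjusted over the list alone), with a mean of -0.12 (adjusted p = 0.224 with an estimated correlation). Olig2 fell by 0.41, whereas Cspg4 had a log2 change of 0.39 that did not pass (adjusted p = 0.0764). Sox10, also counted among the regulatory factors above, had the smallest p of the precursor list, so these lists are not separate evidence.

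Immediate early genes, which neurons induce with activity, were lower in the same libraries: 10 of 25 fell (16 adjusted over the list alone), with a mean of -0.69 (adjusted p = 0.141 with an estimated correlation). This list was fixed as a check of tissue quality, and its mean also differed by 0.48 between the control genotypes. Whether its change reflects neuronal activity or the handling of the tissue was not tested. Arc fell by 2.04 (SE 0.330), Fos by 1.48 (SE 0.278), Junb by 1.19 (SE 0.169), Dusp1 by 1.13 (SE 0.180) and Npas4 by 1.09 (SE 0.247). Markers of striatum, the tissue beneath the cortex, were also lower on average. None of the 23 measured passed over all genes, 20 were lower adjusted over the list alone, and the mean was -0.83 (camera adjusted p = 5.10e-17; adjusted p = 0.224 with an estimated correlation). Adora2a (-1.43, adjusted p = 0.0677), Rgs9 (-1.13, adjusted p = 0.0581) and Drd1a (-0.89, adjusted p = 0.0626) were among its members. Further lists called lower were those of Hippo and YAP targets (mean -0.14; adjusted p = 0.189 with an estimated correlation; Amotl2 fell by 0.51), heat shock (-0.12; 0.502) and cholesterol biosynthesis (-0.08; 0.594). Lists called higher were fibroblast and meninges (mean 0.24), cell cycle (0.14), interferon response (0.14), endothelial cell (0.11), cytoplasmic ribosomal protein (0.09) and nuclear oxidative phosphorylation (0.07). No member of these 6 passed over all genes, and with an estimated correlation their adjusted p lay between 0.342 and 0.594. Without Control replicate 1 the means of fibroblast and meninges (0.08), interferon response (0.07) and cholesterol biosynthesis (-0.04) were no longer called, nor was heat shock (-0.06) without Control replicate 4. Without Prkci cKO replicate 1 the calls of cytoplasmic ribosomal protein (0.02), nuclear oxidative phosphorylation (0.02) and cell cycle (0.08) ended, and without Control replicate 3 the ribosomal mean was 0.06. The other lists had means from -0.08 to 0.20 and were not called.

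In all, 230 of 14330 genes passed in Prkci cKO against controls, 14 higher and 216 lower. Snupn, a nuclear import adaptor for small nuclear ribonucleoproteins, rose to 35.4 ± 1.34 against 11.2 ± 0.386 (SD, n = 4 each; log2 change 1.62, adjusted p = 8.92e-09). Odf3l1, a low gene named after its values were seen, rose to 0.90 ± 0.356 against 0.0200 ± 0.0231 (SD, n = 4 each; 1.40 on the log2(value + 0.5) scale, adjusted p = 0.00284). Imp3 (0.57), Ltbp4 (0.34), Unc119 (0.30), Wnt4 (0.30), Ptpn9 (0.27) and Septin 9 (0.26, listed under a date-like name) also rose, and Dynlt1b (0.67) rose but has near-identical copies whose reads may be split. Lower genes outside these lists included Cd4 (-1.59), Sh3rf2 (-1.48), Nipal4 (-1.09) and Arhgef19 (-1.07). The count was 148 without Prkci cKO replicate 1, 95 without its replicate 2, 132 against the f/f controls alone and 346 with array weights. With a per-library striatum score as a covariate it was 8, and with an immediate early gene score 24, both chosen after seeing the data. In both scores every control lay above every Prkci cKO library, so these fits cannot separate score from group.

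**Figure D2:**
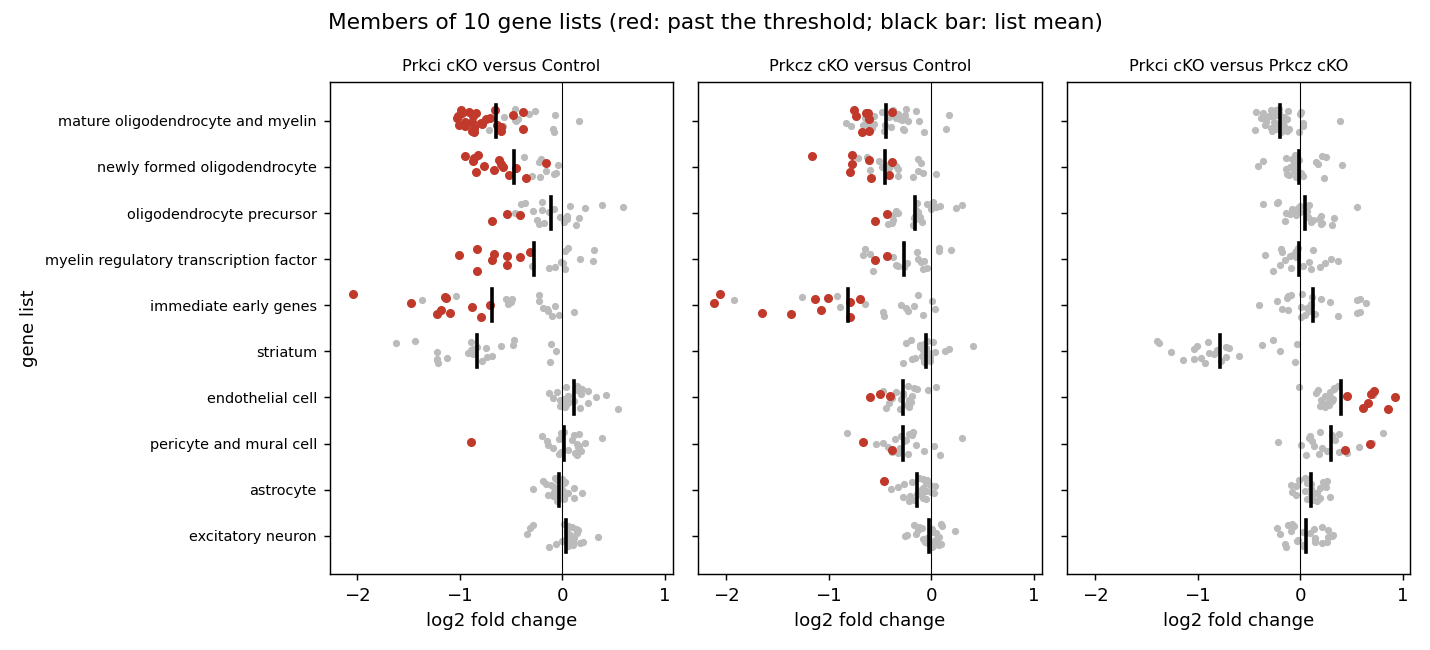
Log2 fold change (horizontal axis) of each measured member of 10 gene lists (vertical axis) in the 3 comparisons, with members past the threshold in red, others in grey and the list mean as a black bar. The mature oligodendrocyte list has a mean of -0.65 in Prkci cKO and -0.45 in Prkcz cKO, and the striatum list -0.83 and -0.05.

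The second comparison asked the same of Prkcz. Newly formed oligodendrocyte genes were lower in Prkcz cKO than in controls. Gpr17 was 76.9 ± 4.29 (SD, n = 3) against 131 ± 4.19 (SD, n = 4), a log2 change of -0.77 (SE 0.068, limma adjusted p = 1.86e-04). Tns3, which links integrins to actin, fell by 0.59 (SE 0.078, adjusted p = 0.00872), Bcas1 by 1.17 (SE 0.184, adjusted p = 0.0191) and Cnksr3 by 0.60 (SE 0.094, adjusted p = 0.0179). Of 24 genes in that list 8 fell (19 adjusted over the list alone), with a mean of -0.45, and the call held with an estimated correlation (adjusted p = 0.0187).

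Of 40 mature oligodendrocyte and myelin genes, 8 fell over all genes, and 31 were lower and 1 higher adjusted over the list alone. The mean was -0.45 (adjusted p = 0.175 with an estimated correlation). Adamts4 (-0.76), Ermn (-0.73), Ugt8a (-0.67) and the carbonic anhydrase Car2 (-0.39) fell, while Mbp (-0.83, adjusted p = 0.114), chosen after its values were seen, did not pass. Sox10 (-0.55) and Olig1 (-0.43) were the 2 of 20 myelin regulatory transcription factors that fell, with a list mean of -0.26 (adjusted p = 0.0842 with an estimated correlation). The lists of oligodendrocyte precursors (2 of 24 fell, mean -0.16) and of sphingolipid and fatty acid synthesis (2 of 25 fell, mean -0.20) were called, at adjusted p = 0.112 and 0.108 with an estimated correlation. Sox10 belongs to both the precursor list and the list of regulatory factors, so these are not separate evidence.

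Vascular genes were lower in Prkcz cKO, and whether Ng2-Cre acted in vascular cells was not examined here. Flt1 and Kdr, receptors for vascular endothelial growth factor, fell by 0.50 (SE 0.071, adjusted p = 0.00964) and 0.60 (SE 0.119, adjusted p = 0.0379), and Gpr116 by 0.40 (SE 0.082). Those 3 of 25 endothelial genes passed over all genes and 18 adjusted over the list alone, with a mean of -0.28 (adjusted p = 0.0779 with an estimated correlation). Among 22 pericyte and mural cell genes, Rgs5 (-0.39) and Mcam (-0.67) fell, Mcam as in Prkci cKO (-0.89, adjusted p = 0.00226), and the mean was -0.28 (adjusted p = 0.0972 with an estimated correlation). In the astrocyte list, Aqp4, the water channel of astrocyte endfeet, fell by 0.46, and the mean over 25 genes was -0.14 (adjusted p = 0.340 with an estimated correlation). The Hippo and YAP target list had no member past the threshold and 21 of 21 below 0, with a mean of -0.20, and was called with an estimated correlation (adjusted p = 0.0402).

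Immediate early genes were also lower: 10 of 25 fell (18 adjusted over the list alone), with a mean of -0.81 (adjusted p = 0.108 with an estimated correlation). As in Prkci cKO, neuronal activity and tissue handling were not told apart. Fos (-2.12, SE 0.300), Arc (-2.06, SE 0.356), Npas4 (-1.64, SE 0.267), Nr4a1 (-1.37, SE 0.275) and Egr1 (-1.13, SE 0.208) were among those that fell. The striatum list had a mean of -0.05 and was not called (camera adjusted p = 0.844), but this value depended on single libraries. Without Prkcz cKO replicate 3 the mean was -0.39 and the list was called (camera adjusted p = 1.94e-07). It was 0.14 and 0.11 without Prkcz cKO replicates 1 and 2, and -0.18, 0.02 and 0.03 without Control replicates 2, 1 and 4, and was not called in these. Other lists called lower were interferon response (mean -0.14), reactive astrocyte (-0.13), node of Ranvier and paranode (-0.09, with Nfasc lower by a log2 change of -0.42) and cholesterol biosynthesis (-0.08), with adjusted p between 0.412 and 0.667 with an estimated correlation. Choroid plexus and ependyma (0.40) and nuclear oxidative phosphorylation (0.10) were called higher, at adjusted p = 0.714 and 0.412 with an estimated correlation. The choroid plexus mean was 0.03 without Control replicate 1, 0.67 without Control replicate 2 and 0.23 without Prkcz cKO replicate 2, and the first and last ended its call. Calls also ended for cholesterol biosynthesis without Control replicate 1 (-0.04) or Prkcz cKO replicate 1 (-0.04), for reactive astrocyte without Control replicate 3 (-0.06) and for node of Ranvier without Prkcz cKO replicate 3 (-0.05).

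In all, 93 genes passed in Prkcz cKO against controls, 4 higher and 89 lower. The genes that rose were Snupn (1.62, SE 0.068), Imp3 (0.74, SE 0.071), Scg5 (0.34, SE 0.067), a secretory granule chaperone, and Odf3l1, named after its values were seen, which was at 0.0200 ± 0.0231 in controls and 1.13 ± 0.306 (SD, n = 3) in Prkcz cKO. The count was 13 without Prkcz cKO replicate 2 and 13 without its replicate 3, the shallowest library, 27 without Control replicate 1 and 50 without Control replicate 2. It was 59 against the f/f controls alone, 30 without a variance trend, 29 with only the 2 groups fitted and 2 with an immediate early gene score as a covariate chosen after seeing the data. In that score every control lay above every Prkcz cKO library, so that fit cannot separate score from group.

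Both knockouts shared lower genes. Gpr17, Cnksr3, Plxnb3, Sox10, Olig1, Ermn, Adamts4, Ugt8a, Arc, Fos, Junb, Dusp1, Npas4 and Sik1 were among 57 genes lower in both, and Snupn, Imp3 and Odf3l1 were the 3 genes higher in both. Independent lists of these sizes would share 1.34 lower and 0.00391 higher genes, and 100 simulations of unchanged groups against the same controls shared 0 of either, but called a mean of only 1.04 and 0.53 genes, so that count is no reference for lists of these sizes. With the controls split between the comparisons, 1 to 43 lower and 2 to 3 higher genes were shared. In these splits 1 to 184 genes were called lower in Prkcz cKO, and independent lists would share 0.00733 to 1.25 lower genes. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.470 (Spearman's rho 0.340) against 0.468 and 0.438 in the simulations, and at 0.0834 to 0.234 with split controls. The covariance was 0.0153 against a simulated 0.00870, and lay within the central 95% of simulated values (0.00126 to 0.0178). For r this range was 0.0763 to 0.834.

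**Figure D3:**
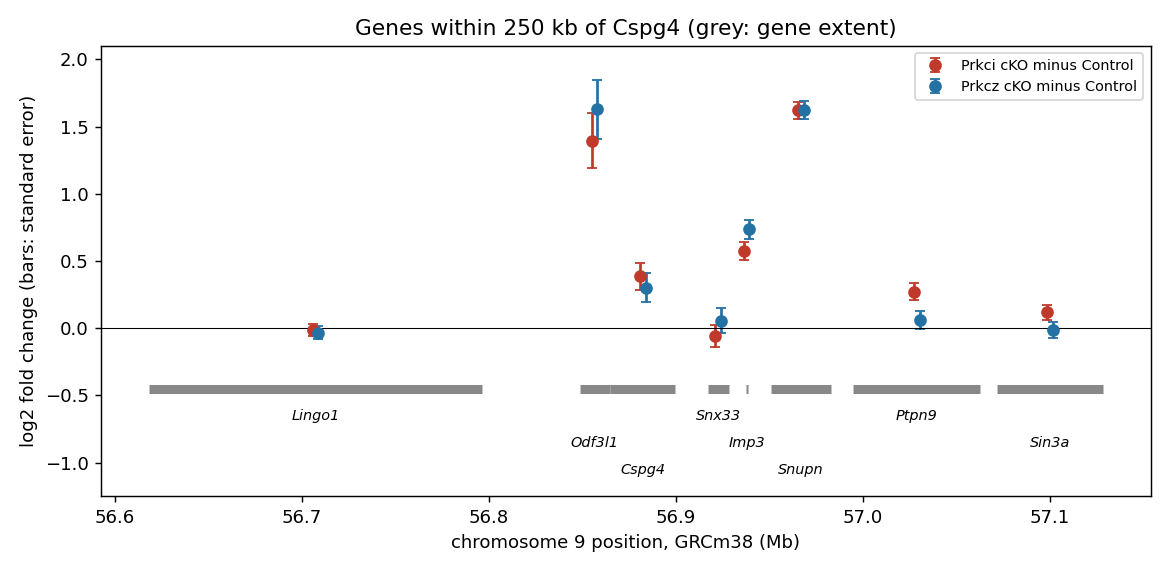
Log2 fold change against controls (vertical axis, bars give the SE) of the 8 genes tested within 250 kb of Cspg4, by position on chromosome 9 (horizontal axis, Mb, GRCm38), with points of the 2 knockouts set slightly apart and gene extents in grey. Snupn is at 1.62 in both knockouts, while Lingo1 and Snx33 lie between -0.06 and 0.06.

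The third comparison tested the knockouts against each other. Vascular genes were higher in Prkci cKO than in Prkcz cKO: Kdr was 27.4 ± 2.73 (SD, n = 4) against 14.3 ± 2.72 (SD, n = 3), a log2 difference of 0.92 (SE 0.119, limma adjusted p = 0.00840). Vwf, the platelet-binding protein of endothelium, differed by 0.85 (SE 0.140), Cd93 by 0.82 (SE 0.115), Eltd1 by 0.72 (SE 0.108), Flt4 by 0.69, Flt1 by 0.68 and Ptprb by 0.66. In controls, Kdr lay between these values at 21.8 ± 1.97 (SD, n = 4). Of 25 endothelial genes, 7 were higher over all genes and 22 adjusted over the list alone, with a mean of 0.39 (adjusted p = 0.0602 with an estimated correlation). Of 22 pericyte and mural cell genes, Myl9 (0.68) and Rgs5 (0.44) were higher, with a mean of 0.29 (adjusted p = 0.178 with an estimated correlation). The intermediate filament genes Nes (0.86) and Vim (0.44) were the 2 of 19 reactive astrocyte genes that were higher, with a mean of 0.23 (adjusted p = 0.354 with an estimated correlation), and the clock gene Per2 was higher by 0.68.

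Myelin genes were not told apart between the knockouts at the level of single genes. None of the 40 mature oligodendrocyte and myelin genes passed over all genes, and 2 were lower adjusted over the list alone. The mean was -0.20, called by camera and not with an estimated correlation (adjusted p = 0.693). Aspa differed by -0.43 (SE 0.110, adjusted p = 0.130) and Cldn11 by -0.36 (SE 0.125, adjusted p = 0.216), and the newly formed oligodendrocyte list had a mean of -0.01 and was not called (camera adjusted p = 0.805). The striatum list was lower in Prkci cKO, with a mean of -0.78, 0 of 23 members past the threshold and 16 adjusted over the list alone (adjusted p = 0.471 with an estimated correlation); without Prkcz cKO replicate 3 the mean was -0.44. Lists called higher also included fibroblast and meninges (0.30), interferon response (0.28), astrocyte (0.10), cytoplasmic ribosomal protein (0.10), circadian clock (0.10) and microglia (0.07), at adjusted p from 0.250 to 0.929 with an estimated correlation. Without Prkci cKO replicate 1 the means of cytoplasmic ribosomal protein (0.02) and microglia (0.05) were no longer called, and without Prkcz cKO replicate 3 the former was 0.06.

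In all, 43 genes passed between the knockouts, 34 higher and 9 lower in Prkci cKO. Lower genes included Arhgef19 (-0.64), Gpr153 (-0.61), Pold4 (-0.51), the glycolytic enzyme gene Eno1 (-0.41), Fbxo44 (-0.40) and Slc2a5, a fructose transporter named after its values were seen, at 0.623 ± 0.164 (SD, n = 4) against 3.07 ± 0.792 (SD, n = 3). Of the 9, 6 lie within 20 Mb of Prkcz on chromosome 4. The count was 10 without Prkci cKO replicate 1, 14 without its replicate 2, 19 without its replicate 4, 152 without Prkcz cKO replicate 1 and 16 without its replicate 3. It was 112 with array weights and 1 with a striatum score as a covariate chosen after seeing the data. In that score every Prkcz cKO library lay above every Prkci cKO library, so that fit cannot separate score from group.

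**Figure D4:**
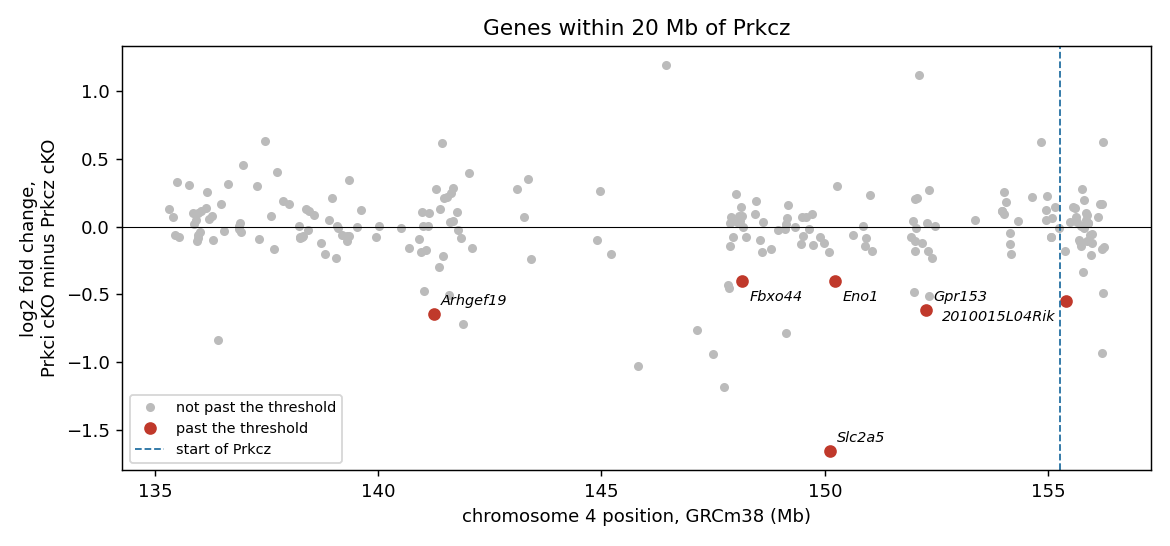
Log2 fold change of Prkci cKO minus Prkcz cKO (vertical axis) of the 221 genes tested within 20 Mb of Prkcz, by start position on chromosome 4 (horizontal axis, Mb, GRCm38), with genes past the threshold in red and a dashed line at the start of Prkcz. The 6 genes past the threshold are all lower in Prkci cKO, Slc2a5 the most at -1.66.

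The controls were also compared by genotype label, with a count that depended on the fit. In the 2 Pkcz f/f controls against the 2 Pkcz f/+ controls, 22 genes passed, 9 higher and 13 lower; the genes named here were chosen after their values were seen. Gabra2, a subunit of the GABA-A receptor, was 100 against 44.1 (log2 difference 1.18, SE 0.106, limma adjusted p = 8.41e-04). The endoplasmic reticulum chaperone genes Hspa5 (0.60), Pdia6 (0.52), Calr (0.37) and Hsp90b1 (0.37) were higher, and Ndn (-0.75) and Noc2l (-0.55) lower. The mature oligodendrocyte list had a mean of -0.32, the unfolded protein response list 0.26, the heat shock list 0.28 and the immediate early gene list 0.48, with adjusted p = 0.298, 0.165, 0.10 and 0.228 with an estimated correlation. Other lists called higher were fibroblast and meninges (0.44), blood (0.43), interferon response (0.22), reactive astrocyte (0.18), microglia (0.12), glucocorticoid and hypoxia response (0.12) and endothelial cell (0.09). Other lists called lower were cytoplasmic ribosomal protein (-0.17), myelin regulatory transcription factors (-0.16), sphingolipid and fatty acid synthesis (-0.14), cholesterol biosynthesis (-0.13), node of Ranvier and paranode (-0.09) and nuclear oxidative phosphorylation (-0.08). With an estimated correlation the adjusted p of these lists lay between 0.165 and 0.776. Without Control replicate 1 the means were 0.15 for fibroblast and meninges, 0.11 for blood, 0.13 for interferon response, 0.09 for reactive astrocyte, 0.05 for endothelial cell, -0.08 for cholesterol biosynthesis and -0.04 for node of Ranvier, and of these only fibroblast and meninges and cholesterol biosynthesis were still called. The immediate early gene mean was 0.73 without Control replicate 1 and 0.23 without Control replicate 2, where fibroblast and meninges was 0.72, blood 0.75 and node of Ranvier -0.13. Reactive astrocyte (0.05) and endothelial cell (0.04) lost their calls without Control replicate 3 and node of Ranvier (-0.05) without Control replicate 4, where the former 2 were 0.31 and 0.15. The count was 5, 40, 7 and 9 without Control replicates 1, 2, 3 and 4, where the library left alone was assumed to vary like the other groups. In limma it was 12 without a variance trend, 70 with only the controls fitted, 0 with the replicate block (824 genes at an unadjusted p under 0.05) and 0 with the immediate early gene score as a covariate (1007 genes), all chosen after seeing the data.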

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

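The tests on Snx33, on libraries with Cre alone, on positions near Cspg4, on the frequency of calls near Prkcz and on the f/f controls were chosen after the results were seen. The other tests here were written down before they were run, although Noc2l and Arhgef10l, 2 genes near Prkcz, had been seen in the controls.

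Regrouping of the libraries was tested for each count. In Prkci cKO against controls, 1 of 35 splits, the real one, gave as many as 230 genes, and the highest other split gave 2. In Prkcz cKO against controls, 1 of 35 splits gave as many as 93, and the highest other gave 14. Between the knockouts, 1 of 35 gave as many as 43, and the highest other gave 3. For each count only the real split gave as many genes, and 1 of 35 is the smallest share that this test can give. The test does not cover factors that coincide with the groups, such as Cre and line.

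The first pattern is the rise of Snupn, Imp3 and Odf3l1, all within 250 kb of Cspg4, in both knockouts. One unbroken extra copy of this stretch on the Cre transgene, with each gene rising alike, is argued against by Snx33, which lies between Odf3l1 and Imp3 and was at -0.0570 (SE 0.085) in Prkci cKO and 0.0554 (SE 0.091) in Prkcz cKO, while Imp3 rose by 0.57 and 0.74. Cspg4 itself did not pass, at 0.39 and 0.30. Extra copies of part of the stretch, and a response to the loss of either kinase, both stay open as hypotheses, since 0 libraries carried Cre without a floxed kinase. Snupn differed by -0.00 (SE 0.068) between the knockouts.

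The second pattern is the lower expression of genes on distal chromosome 4 in Prkci cKO, where 6 of 221 genes within 20 Mb of Prkcz were called between the knockouts, although of 37 genes there at p under 0.01 in limma 23 were lower and 14 higher. A segment linked to the floxed Prkcz allele was the candidate explanation. For an effect growing with its copies, it predicted that genes differing between the knockouts would differ the same way between f/f and f/+ controls. They did so for 35.1% of 37 genes in the window against 57.0% of 625 elsewhere, which gave no sign of such growth. The test does not decide on a linked segment as such, since few controls carried each label and all carried the floxed allele. The Fisher's exact odds ratio of calls in the window (10.3, 95% interval 3.50 to 24.9) counts the calls that drew attention to it and decides nothing. At p under 0.01 in limma, 37 of 221 window genes differed, against 625 of all other genes among the 13868 with a position. Most of the 37 were not among the 6 calls. This larger share argues against a response to Prkci loss that is independent of position as the whole account. A background difference carried alike by f/f and f/+ animals was not tested.

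The third pattern is the lower expression of myelin genes in both knockouts. The striatum list mean was -0.83 (SE over libraries 0.288) in Prkci cKO and -0.05 (SE 0.311) in Prkcz cKO. The latter was -0.39 without Prkcz cKO replicate 3, and 0.14 and 0.11 without its replicates 1 and 2. Less striatal tissue in the punches could not be excluded: with the striatum score as a covariate the mean of the mature oligodendrocyte list was -0.58 (SE 0.179) in Prkci cKO and -0.44 (SE 0.135) in Prkcz cKO, against -0.65 and -0.45 without it. Against the f/f controls the means were -0.49 (SE 0.122) and -0.29 (SE 0.129). Both lists were thus still lower on average against the f/f controls alone. Neither mean, plus 2 SE, stayed beyond the bound set for this test (-0.32 in Prkci cKO and -0.22 in Prkcz cKO). High myelin in the f/+ controls could therefore not be excluded in either knockout. An effect of the kinases on oligodendrocytes stays open beside these, confounded with Cre and line.

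Single libraries stood apart from their group in 6 of 186 groups of 4 tested, where chance gives about 1 in 20. Arc was 108 in Control replicate 2 against 260 to 264 in the other controls. Flt1 was 45.8 in Control replicate 3, Aqp4 138 in Control replicate 1 and Fbxo44 63.5 in Control replicate 2. Wnt4 was 36.0 in Prkci cKO replicate 2, and Nr4a1 was 54.1 in Prkci cKO replicate 4.

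The knockouts differed by the direct test in these genes, as Prkci cKO minus Prkcz cKO on the log2 scale. No control of the Prkci line was among these samples, so this difference may be one of line or of kinase. The difference was positive in Kdr (0.92), Nes (0.86), Vwf (0.85), Cd93 (0.82), Eltd1 (0.72), Flt4 (0.69), Flt1 (0.68), Per2 (0.68), Myl9 (0.68), Ptprb (0.66), Vim (0.44) and Rgs5 (0.44). It was negative in Slc2a5 (-1.66), Arhgef19 (-0.64), Gpr153 (-0.61), Pold4 (-0.51), Eno1 (-0.41) and Fbxo44 (-0.40).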

How the results depend on the processing

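Covariates and left-out regions were chosen after seeing the data. So were, for lists, the alternatives other than correlation, fry, block and left-out libraries. For similarity, those other than split controls and left-out libraries were chosen then, and for control genotypes all but left-out libraries. edgeR and DESeq2 were planned and not run, as no counts were recovered. Of 120 gene values examined, 11 kept their direction and side of the threshold under every alternative run, 95 lost a call in at least 1 and 11 gained one. The cause was not tested unless stated. With a fold threshold, which leaves fewer genes, the counts were 143 in Prkci cKO, 48 in Prkcz cKO and 26 between the knockouts. Array weights gave 346 genes in Prkci cKO and 112 between the knockouts. Against f/f controls alone, with fewer samples, 132 and 59 passed. For Prkcz cKO the count was 30 without a trend and 29 with only the 2 groups fitted. With the striatum score as a covariate the count was 8 in Prkci cKO and 1 between the knockouts. With the immediate early gene score it was 24 in Prkci cKO and 2 in Prkcz cKO. In each of these covariate fits the scores of the groups compared did not overlap, so a lower count cannot be assigned to the score.

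Leaving out one library gave 95 to 211 genes in Prkci cKO, 13 to 77 in Prkcz cKO, 10 to 152 between the knockouts and 5 to 40 between the control genotypes. Between the control genotypes, 12 genes passed without a trend, 70 with only the controls fitted, 0 with the immediate early gene score and 0 with the replicate block, where 1007 and 824 genes had an unadjusted p under 0.05 in limma, against 1802 without either. The immediate early gene scores of the control genotypes did not overlap either.

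The replicate numbers did not clearly pair the libraries, and pairing stays undecided. After removal of each group's mean, same-numbered libraries correlated from -0.186 to 0.196, and 5 of 10 pairs were over 0.1. By this measure 3 of 11 libraries correlated best with their own number. With the replicate block the counts were 263 in Prkci cKO, 69 in Prkcz cKO and 73 between the knockouts.

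With an estimated correlation 1, 2 and 0 lists were called in Prkci cKO, Prkcz cKO and between the knockouts, and with fry 8, 10 and 3. The mature oligodendrocyte list, with means of -0.65, -0.45 and -0.20, lost its call with an estimated correlation in all 3 comparisons (adjusted p = 0.0966, 0.175 and 0.693), and with fry between the knockouts at the same mean (adjusted p = 0.419). Prkci lost its call at -0.29 in Prkci cKO with the immediate early gene score (adjusted p = 0.165) and at -0.40 between the knockouts with the striatum score (adjusted p = 0.0634).

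Some directions reversed. The kinase gene not targeted, whose change passed in neither knockout, was among them: Prkcz in Prkci cKO was 0.0215 against f/f controls, 0.0410 with the striatum score and -0.0737 to 2.97e-05 with a library left out. Prkci in Prkcz cKO was 0.00516 against f/+ controls, 0.0850 with the immediate early gene score and -0.0733 to 0.00205 with a library left out. In Prkci cKO, the test direction turned for cholesterol biosynthesis against f/f controls (mean -0.0141) and for heat shock against f/+ controls (0.0196). With the immediate early gene score it turned for heat shock (0.106), cytoplasmic ribosomal protein (-0.0946) and nuclear oxidative phosphorylation (-0.0386), and in Prkcz cKO for the last (-0.0356) and choroid plexus (-0.244), and between the control genotypes for nuclear oxidative phosphorylation (0.00437). Ptpn9 in Prkcz cKO, not called, was -0.0190 against f/+ controls and -0.0373 with the immediate early gene score. Between the knockouts, where neither was called, Snupn was 0.00498 and Mbp -0.0537 with quantile normalization, and Snupn 0.0120 and Mbp -0.00536 with the replicate block. With the striatum score they were 0.0976 and -0.0385. Snupn was 0.0522 with array weights and 2.67e-04 with the immediate early gene score. With a library left out Snupn lay between -0.0653 and 0.0664 and Mbp between -0.101 and 0.182.

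The correlation of the effects was 0.0995, 0.151, 0.192 and 0.0834 with control replicates 1 and 2, 1 and 4, 2 and 4, or 3 and 4 used for Prkci cKO, and 0.221 and 0.234 with 1 and 3 or 2 and 3. Prkcz cKO replicate 3 had the lowest depth, about 14810000 reads, and the 2 comparisons with Prkcz cKO called 13 and 16 genes without it.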

Other observations

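Tissue outside the cortex varied between libraries of one group. The choroid plexus and ependyma score, a mean of centred log2 values, ran from -1.31 to 0.62 in the 4 controls (SD 0.81), and the fibroblast and meninges score from -0.58 to 0.28 (SD 0.36), against SDs of 0.21 and 0.07 in Prkci cKO. Both low ends were Control replicate 1. Ttr, the transthyretin gene of choroid plexus, was 474 ± 320 (SD, n = 4) in controls and 664 ± 185 (SD, n = 3) in Prkcz cKO, a log2 change of 0.88 that did not pass in limma (adjusted p = 0.479).

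Neuronal lists were close to 0. The excitatory neuron list had a mean of 0.04 in Prkci cKO and -0.02 in Prkcz cKO, and the inhibitory neuron list 0.01 and 0.04, with 0 of 25 members past the threshold in each case and no call by camera. The list of polarity complex and atypical kinase partners had means of -0.04 and -0.07 and was not called by camera. It was called lower by fry in both knockouts (fry adjusted p = 0.0246 and 0.0180). Of its 27 measured genes, 1 was lower past the threshold in Prkci cKO and 0 in Prkcz cKO. Whether the fry calls rest on the targeted kinase genes was not tested.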
